A study of Homo sapiens with 12 samples.

How the data were processed

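Total RNA from 2 human prostate cell lines was labelled with biotin and hybridised to 1-colour Illumina bead arrays, per the labels' protocols. RWPE1 was measured on 8 arrays in 4 groups of 2 (GFP or GFP-ERG, at 48 h or 72 h after transfection). VCaP was measured on 4 arrays of another array design, 2 with a scramble shRNA and 2 with an ERG shRNA after selection. The labels give the group, time and array number of every array, and no array was left out.

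The deposited values of both tables were taken to be log2 signals from their range: they run from 5.95 to 15.1 in RWPE1 and from 7.44 to 15.4 in VCaP. The range alone cannot tell log2 from a similar transformed scale, and all fold changes rest on this reading. The software, background correction and normalization that the authors used are not given in the sources used here. The deposited log2 values have nearly equal distributions within a table. Sorted values of an array lay within 0.0391 of the mean sorted values in RWPE1 and within 0.0002 in VCaP, which is what quantile normalization by the authors leaves. They were therefore used as deposited, with no further normalization and no floor. The median was 7.23 to 7.24 in RWPE1 arrays and 7.75 in VCaP arrays. Each median lies close to the bottom of its scale. No background appears to have been subtracted, so that fold changes of dim probes are smaller than the changes in RNA behind them. No detection p-values were used here. Both tables were normalized separately, and every test was made within a table.

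Probes were named from the platform annotation supplied with the values, with symbols looked up through Entrez identifiers in the RefSeq gene table of assembly GRCh38.p14, which changed 0 symbols. In RWPE1, 18332 of 20589 probes had 1 gene symbol, 0 had several and 2257 had none. In VCaP, 21833 of 24525 probes had 1 symbol, 0 had several and 2692 had none. A gene was represented by its probe with the highest mean over all arrays of the table, which gave 16591 genes in RWPE1 and 16922 in VCaP. There were 0 columns of samples outside this series.

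Differences were fitted with limma version 3.58.1 in R version 4.3.3 (lmFit, contrasts.fit and eBayes, no trend, not robust), 2-sided, with Benjamini-Hochberg adjustment over all genes of a table and a threshold of 0.05. All 8 RWPE1 arrays entered 1 fit of group means, and the 4 VCaP arrays another. The comparisons were ERG shRNA against scramble shRNA, GFP-ERG against GFP at 48 h, at 72 h and as the mean of both times, the difference of the GFP-ERG effect between the times, and 72 h against 48 h in GFP cells. Standard errors (SE) of log2 fold changes are those of limma after moderation. Tests of 28 gene lists were made with camera at its preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. With an estimated correlation, camera also takes its p-values from the residual degrees of freedom, 2 in VCaP and 4 in RWPE1. Few lists can pass on so few, so a call lost there need not be due to correlation between genes. Overlaps of calls were tested with Fisher's exact test, 2-sided, over 16251 genes measured in both tables, or over the 16591 genes of RWPE1. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.

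The labels say that transfections were made in duplicate, but they do not say which step separates the arrays of a group. The p-values of limma and fry measure the spread between these arrays. Those of camera at its preset correlation and of Fisher's exact test are taken across genes, which are not independent replicates. The number of arrays, 2 per group, limits the precision. On simulated data with 200 changed genes, the VCaP fit on 16922 genes recovered 64.0% of changes of 1 log2 unit and 6.00% of changes of 0.5. The RWPE1 fit on 16591 genes recovered 100% of changes of 0.5 at 48 h, 99.0% at 72 h, 100% for the mean of both times, and 83.0% for the difference between times. The simulated noise was independent between genes and equal in spread between groups. In the VCaP data the SD of the difference within a pair was 0.243 for ERG shRNA and 0.123 for scramble. The recovery rates therefore need not hold for these data.

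The tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. ERG (every probe), FZD4, HDAC1, CDH1, VIM and PLAU are reported whatever their values. For the VCaP comparison and for the mean of both times in RWPE1, the 10 highest and 10 lowest fold changes were named. They were taken among genes past the threshold whose groups of arrays did not overlap and whose higher group lay at or above the median of all probes. For each time alone the limit was 5, as it was for the difference between times and for 72 h against 48 h, both of which used the threshold alone. Up to 4 members of a list that passed, or 2 where none did, and up to 10 genes per overlap were open to naming. Genes linked to X inactivation or the Y chromosome were not named. The alternatives were quantile normalization, median centring, a floor of 6, a filter on dim genes, every probe or the mean of a gene's probes, a trended and robust variance, stricter thresholds, a block for array number, the arrays of the comparison alone, other set tests, and leaving out each array.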

Results

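Genome-wide mRNA levels were compared between prostate cells with raised or targeted ERG. ERG is a transcription factor of the ETS family that many prostate cancers express through gene fusions. RWPE1 is an immortalised, non-cancerous prostate epithelial line, and it was transfected with GFP or with ERG fused to GFP. VCaP is a prostate cancer line that carries a TMPRSS2-ERG fusion, and it received a lentiviral shRNA against ERG or a scramble shRNA. Each of the 6 groups had 2 arrays. Levels are normalized log2 signals, given as mean ± SD with n = 2 unless stated otherwise. Arrays of a group resembled each other closely in RWPE1, where 0 or 1 gene differed by more than 2-fold within a pair. In VCaP, 4 genes did so between the scramble arrays and 115 between the arrays labelled ERG shRNA.

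ERG itself was examined first, since it checks the labels. In RWPE1, the ERG probe for NM_182918 was higher with GFP-ERG at both times. It read 6.36 ± 0.09 with GFP and 7.31 ± 0.03 with GFP-ERG at 48 h, and 6.31 ± 0.08 and 6.94 ± 0.01 at 72 h. The GFP readings of this ERG probe lay at the 0.928th to 6.86th percentile of their arrays, near the bottom of the scale, so the size of its rise is not exact. The rise of the ERG probe was 0.95 log2 units at 48 h (SE 0.07, limma with Benjamini-Hochberg adjustment over all probes, adjusted p = 2.05e-09) and 0.63 at 72 h (SE 0.07, adjusted p = 1.06e-06). The other RWPE1 probe of ERG, for NM_004449, stayed between 6.91 and 6.94 in the 4 group means. Whether these probes lie within the transfected sequence is not given in the sources used here. In VCaP, the brightest ERG probe, also for NM_182918, read 8.34 ± 0.02 in the scramble arrays and 8.74 ± 0.04 in the arrays labelled ERG shRNA. That probe of ERG was therefore 0.40 log2 units higher in the arrays labelled ERG shRNA, against the direction of the label (SE 0.03, limma with Benjamini-Hochberg adjustment over all probes, adjusted p = 0.0396). Of its alternatives, the block for array number gave adjusted p = 0.0998, the filter on dim genes 0.0515, and the fits without scramble array 1, without scramble array 2 or without ERG shRNA array 2 gave 0.266, 0.326 and 0.0533. The other VCaP probes of ERG, for NM_004449 and NM_182918, read 7.62 and 7.52 in the arrays labelled ERG shRNA and 7.63 and 7.56 in the scramble arrays, near the bottom of the scale. Lower ERG mRNA was thus not measured in the arrays labelled ERG shRNA, and all directions in VCaP refer to the label alone.

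**Figure D1:**
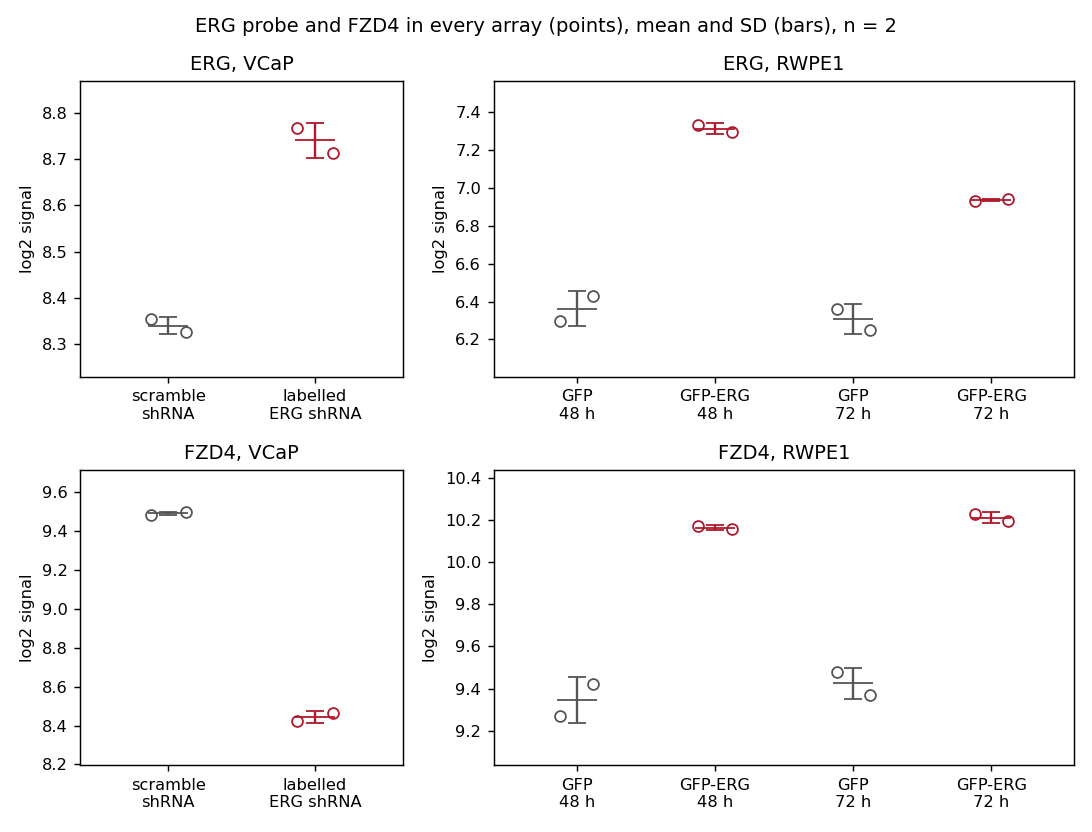
Normalized log2 signal of the NM_182918 probe of ERG (upper panels) and of FZD4 (lower panels) in VCaP (left) and RWPE1 (right); points are single arrays, bars the mean and SD of 2 arrays, and the axes do not start at 0. The ERG probe was higher with GFP-ERG (6.36 against 7.31 at 48 h) and also higher in the arrays labelled ERG shRNA (8.34 against 8.74), while FZD4 was higher with GFP-ERG and lower in the arrays labelled ERG shRNA (9.49 against 8.44).

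The VCaP comparison asked which genes differ when ERG is targeted. The vesicle protein SYT4 was 4.70-fold higher in the arrays labelled ERG shRNA, rising from 9.09 ± 0.12 to 11.33 ± 0.02. CHGA, which encodes the granule protein chromogranin A, was 3.42-fold higher (9.15 ± 0.06 to 10.92 ± 0.02), and CADPS and SNAP25, which act in vesicle exocytosis, were 3.15-fold and 2.59-fold higher. The prostaglandin-degrading enzyme HPGD was 4.45-fold higher and the prostate protein SLC45A3 3.03-fold higher. PRUNE2 (3.61-fold), NAPB (2.57-fold), the neuronal filament gene INA (2.53-fold) and the monoamine oxidase MAOA (2.51-fold) completed the highest 10. Lower genes included MGP, a matrix protein that binds calcium, which went from 10.25 ± 0.05 to 7.87 ± 0.29 (5.22-fold), a level near the bottom of the scale. NDUFA3 and NDUFA1, which encode subunits of respiratory complex I, were 5.17-fold and 4.43-fold lower, and ATP5MC1, which encodes a subunit of ATP synthase, was 4.57-fold lower. The mitochondrial membrane protein ROMO1 was 4.60-fold lower, the chemokine-like CKLF 4.72-fold, the copper chaperone ATOX1 4.55-fold, FKBP11 4.42-fold, the metallothionein MT2A 4.35-fold and the spliceosomal SNRPF 4.34-fold.

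In total 591 of 16922 genes passed adjusted p 0.05 in VCaP (limma, Benjamini-Hochberg), 284 higher and 307 lower in the arrays labelled ERG shRNA. Among those with a change of at least 1 log2 unit, 40 were higher and 151 lower. The smallest adjusted p was 0.0231 (limma, Benjamini-Hochberg), and 3651 genes had an unadjusted p under 0.05. The groups of arrays did not overlap for 52.8% of all genes, where chance gives 33.3%. With a block for array number limma called 0 genes, with 3612 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0899 (Benjamini-Hochberg), while a trended, robust variance gave 1705 genes and the filter on dim genes 1007. Leaving out 1 VCaP array left its group with a single array, so that the spread came from the other pair alone. The pairs were unequal: 115 genes differed by more than 2-fold between the arrays labelled ERG shRNA and 4 between the scramble arrays. The number of calls rose where the scramble pair was left and fell where the ERG shRNA pair was left. It thus followed the spread of the remaining pair, and does not show that the differences rest on the scramble arrays.

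FZD4, a receptor for Wnt ligands, was 2.07-fold lower in the arrays labelled ERG shRNA, from 9.49 ± 0.01 to 8.44 ± 0.03 (log2 fold change -1.05, SE 0.03, limma with Benjamini-Hochberg adjustment, adjusted p = 0.0231). With the block for array number FZD4 no longer passed (adjusted p = 0.0899, limma with Benjamini-Hochberg), nor without scramble array 1 (0.251) or scramble array 2 (0.319), while its change stayed between -1.07 and -1.03. It was the only one of 42 measured Wnt receptors, ligands and transducers to pass. Among 23 Wnt target genes, CCND1 and AXIN2 rose, by 2.11-fold and 1.40-fold, and 0 fell. The Wnt target list passed as higher by fry (Benjamini-Hochberg, adjusted p = 0.0203) but not by camera (Benjamini-Hochberg, adjusted p = 0.792). HDAC1 (log2 fold change 0.05, SE 0.24) and the epithelial cadherin CDH1 (0.11, SE 0.14) did not pass. VIM and PLAU, at 7.54 and 7.60 in the arrays labelled ERG shRNA, lay near the bottom of the scale and did not pass.

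Of 17 neuroendocrine genes measured in VCaP, 4 rose (CHGA, SNAP25, SCG3 and SYP, by 1.77, 1.37, 1.23 and 0.62 log2 units) and 0 fell, and 6 rose when adjusted over the list alone. The neuroendocrine list was higher than other genes (camera, Benjamini-Hochberg, adjusted p = 0.00404), with adjusted p = 0.786 with an estimated correlation. Of 32 androgen receptor targets, 6 rose, among them HPGD, SLC45A3, STEAP2 (2.08-fold) and ACP3 (1.84-fold), and 2 fell. Adjusted over the list alone, 9 rose and 4 fell, and the androgen receptor target list did not pass (camera, Benjamini-Hochberg, adjusted p = 0.0861). Of 18 luminal prostate genes, SLC45A3, ACP3 and CD24 rose and KLK3, which encodes prostate-specific antigen, fell by 0.69 log2 units. The luminal list had a median of -0.02 and a mean of 0.17, and it did not pass (camera, Benjamini-Hochberg, adjusted p = 0.813). By fry, which does not compare a list with other genes, the luminal list (Benjamini-Hochberg, adjusted p = 0.00344) and the androgen receptor targets (adjusted p = 0.0115, fry with Benjamini-Hochberg) did pass as higher. The neuroendocrine list also passed as higher by fry (Benjamini-Hochberg, adjusted p = 0.0370).

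The other lists past the camera threshold in VCaP were lower in the arrays labelled ERG shRNA. Of 32 epithelial junction genes, RAB25, CLDN7 and LSR fell, by 2.52-fold, 2.12-fold and 1.34-fold, and 0 rose (camera, Benjamini-Hochberg, adjusted p = 0.0303). Of 31 interferon response genes, IFITM3, IFI6 and ISG15 fell, by 1.76-fold, 1.45-fold and 1.43-fold (adjusted p = 0.0303 by camera with Benjamini-Hochberg). Of 18 cholesterol synthesis genes, EBP fell 2.28-fold, and 7 fell and 1 rose when adjusted over the list alone (camera, Benjamini-Hochberg, adjusted p = 0.00153). The 29 genes of S phase had a median log2 fold change of -0.49 with 0 past the threshold (camera, Benjamini-Hochberg, adjusted p = 0.00153). Their per-array medians were 8.66 and 9.60 in the arrays labelled ERG shRNA and 10.02 and 9.95 in the scramble arrays. The 39 ribosomal protein genes had a median of -0.30 with 0 past the threshold (camera, Benjamini-Hochberg, adjusted p = 0.00404), and per-array medians of 14.10 and 13.63 against 14.17 and 14.18. With an estimated correlation, 0 of the 28 lists passed in VCaP and 0 had an unadjusted p under 0.05 (camera, Benjamini-Hochberg, adjusted p = 0.786 with an estimated correlation for each of these lists). With 2 residual degrees of freedom, few lists could have passed that test. Cholesterol synthesis lost its call at an estimated correlation of -0.0542, below the preset 0.01, whereas that of S phase was 0.775. Without ERG shRNA array 1 the calls of the S phase, junction and interferon lists ended (camera, Benjamini-Hochberg, adjusted p = 0.498, 0.178 and 0.214). Without ERG shRNA array 2 those of the ribosomal and interferon lists did (camera, Benjamini-Hochberg, adjusted p = 0.680 and 0.0545). The junction call also ended without scramble array 2 (camera, Benjamini-Hochberg, adjusted p = 0.0920), with the block for array number (0.0744) and with the mean of a gene's probes (0.0896), and the interferon call with the block (0.0506) and the filter on dim genes (0.0757). By fry the S phase, ribosomal and junction lists did not pass (Benjamini-Hochberg, adjusted p = 0.384, 0.373 and 0.201). The cholesterol synthesis and interferon lists did pass by fry as lower (Benjamini-Hochberg, adjusted p = 0.00371 and 0.0249). Markers of other cell types did not pass in VCaP: 0 of 12 fibroblast, 0 of 12 endothelial and 0 of 13 leukocyte genes rose or fell.

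The change in VCaP also ran with the span of a gene in the genome (Spearman's rho = 0.32 over 9366 genes, and 0.22 between both arrays labelled ERG shRNA). Set against genes matched on span and level, a comparison chosen after the result was seen, the ribosomal protein genes differed by a median of 0.01 log2 units (95% bootstrap interval -0.21 to 0.13) and the interferon response genes by -0.01 (-0.07 to 0.01). The neuroendocrine genes differed by 0.21 (0.02 to 0.96), the S phase genes by -0.55 (-0.81 to -0.33), the cholesterol synthesis genes by -0.45 (-0.52 to -0.08) and the epithelial junction genes by -0.16 (-0.22 to -0.02). These intervals resample the genes of a list within the same arrays, so they do not measure the spread between arrays. Without ERG shRNA array 1 the median log2 fold change of the S phase genes was -0.02.

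Overexpression in RWPE1 asked which genes ERG changes in cells that lack the fusion. Averaged over both times, SH2D3C, which encodes a signalling adaptor, was 3.67-fold higher with GFP-ERG. It read 7.30 ± 0.10 with GFP and 9.48 ± 0.05 with GFP-ERG at 48 h. APP, the amyloid precursor gene, was 3.25-fold higher on its used probe, while its other probe, at a level of 9.04, changed by 0.15 log2 units and did not pass. The hemoglobin gene HBA1 was 2.93-fold higher, the acute-phase gene CRP 2.88-fold, HECW2 2.77-fold, the hyaluronan-binding CEMIP 2.41-fold and the iron-carrier LCN2 2.38-fold. RASIP1, which acts in blood vessel formation, was 2.34-fold higher, the coagulation inhibitor TFPI 2.31-fold and the cytokine subunit EBI3 2.27-fold. The second probes of TFPI and SH2D3C rose too, by 0.58 and 0.28 log2 units. Lower genes were STRN (3.19-fold), CRB2 (3.09-fold), NCMAP (3.04-fold), TGM6 (2.95-fold), EML1 (2.90-fold), VTI1A (2.89-fold), SLC27A6 (2.89-fold), PDE4DIP (2.80-fold), KCNV2 (2.78-fold) and FCRL6 (2.77-fold). Other probes of EML1, SLC27A6 and PDE4DIP, between 6.30 and 6.94 in level, changed by -0.07 to 0.02 log2 units and did not pass.

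For the mean of both times 2074 of 16591 genes passed (limma, Benjamini-Hochberg), 1132 higher and 942 lower with GFP-ERG, with a median absolute change of 0.22 log2 units among them. At least 1 log2 unit was reached by 17 higher and 28 lower genes. The 4 arrays of each kind did not overlap for 889 of the 2074 genes, and for 8.03% of all genes. Chance gives 2.86% for 8 interchangeable arrays, which those of 48 h and 72 h are not, so that value is only a rough guide. A fit of 2 groups of 4 arrays with no term for time called 192 genes.

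FZD4 was 1.74-fold higher with GFP-ERG (log2 fold change 0.80, SE 0.05, limma with Benjamini-Hochberg adjustment, adjusted p = 8.30e-11), at 9.35 ± 0.11 and 10.16 ± 0.01 at 48 h and 9.42 ± 0.07 and 10.21 ± 0.03 at 72 h. Of 43 Wnt receptors, ligands and transducers, FZD4, WNT7A (1.15-fold) and GSK3B (1.13-fold) rose and 0 fell. The urokinase gene PLAU rose 1.17-fold (SE 0.05 on the log2 scale, limma with Benjamini-Hochberg adjustment, adjusted p = 0.00123), and HDAC1 rose 1.10-fold (adjusted p = 0.0419 by limma with Benjamini-Hochberg adjustment). VIM, at 14.51 ± 0.06 with GFP at 48 h, changed by 0.04 log2 units (SE 0.05), and CDH1, at 6.95 ± 0.07, by -0.01 (SE 0.05), and neither passed. The CDH1 probe read 6.95 to 7.11 in the group means, below the array medians, so it could hardly show a change. VIM lay near the top of the scale, at 15.1. Neither value shows that the gene stayed unchanged.

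Among 29 genes of extracellular proteolysis, 7 rose with GFP-ERG, led by ADAMTS4 (1.92-fold), the plasminogen activator PLAT (0.59 log2 units) and ADAM19 (1.46-fold), and 2 fell, among them TIMP3 (1.19-fold). Of 37 mesenchymal genes, 9 rose, with TNC (1.32-fold), THY1 (1.22-fold), COL6A1 (1.21-fold) and FOXC2 (1.20-fold) the largest, and 1 fell. Of 33 epithelial junction genes, CLDN1 fell 1.38-fold and PKP2 1.27-fold, and 0 rose. Inflammatory genes went both ways: of 31, 8 rose, among them LCN2, CCL2 (1.89-fold) and TNF (1.75-fold), and 8 fell, among them CXCL8 (1.70-fold). Of 12 endothelial markers, TEK (1.66-fold), CLDN5 (1.25-fold) and ICAM2 (1.25-fold) rose and 0 fell. The leukocyte marker CD14 rose 2.04-fold, the only one of 13 to pass, and of 12 fibroblast markers 1 rose and 1 fell. Of 23 genes that respond to TGF-beta and BMP signals, 7 rose, among them ID3 (1.35-fold), SMAD6 (1.32-fold) and ID1 (1.23-fold), and 4 fell. Of 29 heat shock and unfolded protein genes, 8 fell, led by ASNS (1.73-fold) and HSPA6 (1.45-fold), and 1 rose. Of 24 p53 targets and cell cycle inhibitors, 6 rose, among them MDM2 (1.32-fold), and 4 fell, led by BBC3 (1.55-fold) and GADD45A (1.48-fold). Of 37 genes linked to ERG in earlier literature, 8 rose and 3 fell. These counts are to be read beside those over all 16591 genes, of which 1132 rose and 942 fell. Among 12 housekeeping genes, a list meant as a check, 2 rose and 1 fell.

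Adjusted over the list alone, the counts for higher and lower genes were 7 and 3 for proteolysis, 10 and 1 for mesenchymal genes, 3 and 0 for endothelial markers, and 3 and 9 for heat shock genes. Camera called 0 of the 28 lists for the mean of both times, and 6 lists had an unadjusted p under 0.05. The smallest adjusted p was that of the endothelial markers (camera, Benjamini-Hochberg, adjusted p = 0.0945), with adjusted p = 0.476 with an estimated correlation. Fry, which asks whether the genes of a list move on balance one way and does not compare them with other genes, called 8 lists. Proteolysis, endothelial markers, heat shock genes and the genes linked to ERG in literature each had adjusted p = 0.00622 (fry, Benjamini-Hochberg).

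**Figure D2:**
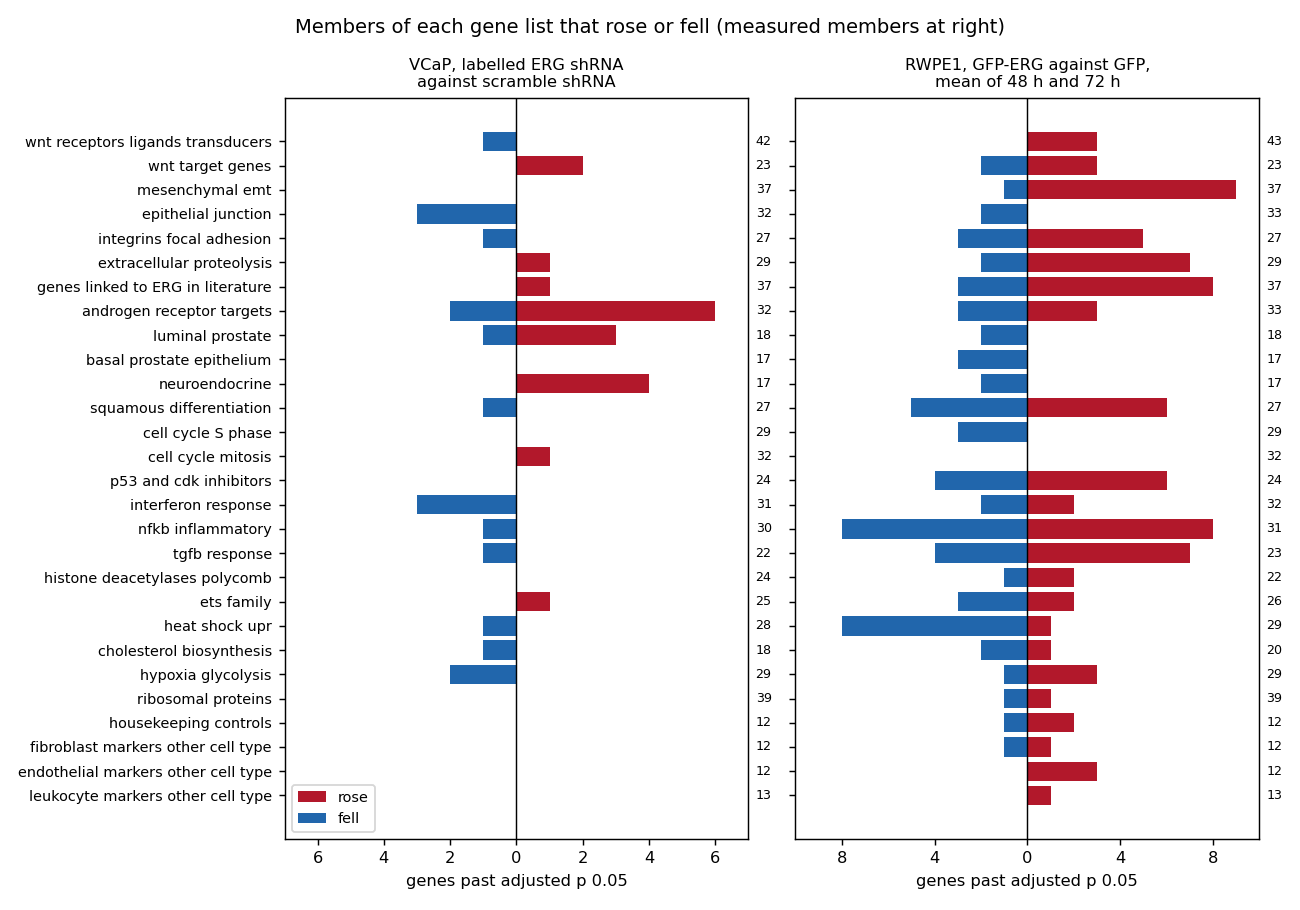
Number of measured members of each of the 28 gene lists that rose (red, right) or fell (blue, left) past adjusted p 0.05, in VCaP for the arrays labelled ERG shRNA against scramble (left panel) and in RWPE1 for GFP-ERG against GFP as the mean of both times (right panel); the number at the right of each row is the members measured. Androgen receptor targets have the most rises in VCaP (6), and mesenchymal genes the most in RWPE1 (9), as counts and not as shares of the members measured.

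At 48 h alone, 1459 genes passed (limma, Benjamini-Hochberg), 807 higher and 652 lower with GFP-ERG, and at 72 h 1029 passed, 530 higher and 499 lower. At 48 h SH2D3C was 4.51-fold, HBA1 4.02-fold, CRP 3.76-fold, HECW2 3.61-fold and APP 3.58-fold higher, and CRB2 3.01-fold and EML1 2.92-fold lower. At 72 h SH2D3C was 2.98-fold, APP 2.95-fold, SHISA2 2.81-fold, the Notch target HEY1 2.61-fold and TFPI 2.57-fold higher, and NCMAP 3.60-fold, STRN 3.55-fold and IFNB1, which encodes interferon beta, 3.16-fold lower. Calls at the 2 times shared 303 higher genes, where 25.8 would be expected of independent lists (odds ratio 41.2, 95% interval 33.8 to 50.3). They shared 314 lower genes against 19.6 expected (odds ratio 78.9, interval 63.6 to 98.2), while 3 and 6 genes were called in opposite directions. Leaving out 1 array moved the odds ratio for higher genes between 29.5 (without GFP array 1 of 72 h) and 90.2 (without GFP array 2 of 72 h), and that for lower genes between 56.1 (without GFP-ERG array 1 of 48 h) and 269 (without GFP array 2 of 72 h). With the filter on dim genes they were 24.5 and 41.9. Those for higher and lower genes were also 66.8 and 127 without GFP array 1 of 48 h, 69.4 and 121 without GFP array 2 of 48 h, and 56.5 and 193 without GFP-ERG array 1 of 72 h. The times had separate GFP arrays, but they shared the estimate of spread and the probes. A signal specific to 1 probe would recur at both times, so the overlap does not exclude it. Across genes, which are not independent replicates, the fold changes correlated with Pearson's r = 0.67 and Spearman's rho = 0.38. The S phase list was lower at 48 h, where POLA1 and GINS2 fell (camera, Benjamini-Hochberg, adjusted p = 0.0358), with adjusted p = 0.362 with an estimated correlation. The S phase call ended without GFP array 2 (camera, Benjamini-Hochberg, adjusted p = 0.133) or GFP-ERG array 1 of 48 h (0.141). The endothelial marker list was higher at 72 h (camera, Benjamini-Hochberg, adjusted p = 0.0476), with adjusted p = 0.727 with an estimated correlation. The endothelial call ended with the block for array number (camera, Benjamini-Hochberg, adjusted p = 0.0560), with the arrays of 72 h alone (0.0577), without either GFP array of 48 h (0.0537), without GFP array 1 of 72 h (0.0998) and without GFP-ERG array 1 of 72 h (0.0964). Without GFP array 1 or array 2 of 48 h, 798 and 799 genes passed at 48 h. At 72 h, 532 passed without GFP array 2, 582 without GFP-ERG array 1 and 681 without GFP-ERG array 2 of that time.

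The effect of GFP-ERG itself differed between 72 h and 48 h for 79 genes (limma, Benjamini-Hochberg), 34 higher and 45 lower at 72 h. HEY1, RGS4, SHISA2, the matrix-binding TNFAIP6 and the protease inhibitor SERPINA3 had the largest gains. HEY1 was 0.37 log2 units above GFP at 48 h and 1.39 at 72 h, and RGS4 was 0.03 and 1.02 above it. The elastase inhibitor PI3, the metallothionein MT1F, the carbonic anhydrase CA2, HBA1 and CYP1A1 had the largest losses. PI3 was 1.52 log2 units above GFP at 48 h and 0.09 at 72 h, and MT1F 1.11 above at 48 h and -0.11 at 72 h. The inflammatory list gained between the times, with CXCL8 and TNFAIP2 past the threshold (camera, Benjamini-Hochberg, adjusted p = 0.00312). The S phase list gained too, with 0 members past it (camera, Benjamini-Hochberg, adjusted p = 0.00312), and both had adjusted p = 0.531 with an estimated correlation. The call of the inflammatory list ended without GFP-ERG array 2 of 48 h (camera, Benjamini-Hochberg, adjusted p = 0.105). The count of 79 genes became 37 and 38 without GFP array 1 or 2 of 48 h, 32 without GFP array 2 of 72 h, 144 without GFP-ERG array 2 of 48 h, and 46 without either GFP-ERG array of 72 h.

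More genes differed between 72 h and 48 h in GFP-transfected RWPE1 than between GFP-ERG and GFP. Anything else that differed between the arrays of 48 h and 72 h cannot be told apart from time. MT1M, which encodes a metal-binding metallothionein, rose from 7.63 ± 0.02 at 48 h to 13.10 ± 0.07 at 72 h (44.4-fold), and its relatives MT1G, MT1B and MT1F rose 18.4-fold, 11.3-fold and 7.70-fold. The fatty acid carrier FABP4 rose 9.33-fold. PRSS3 fell 3.42-fold, the decoy receptor TNFRSF6B 2.76-fold, the Wnt inhibitor DKK1 2.47-fold, the zinc transporter SLC39A10 2.44-fold and IFNB1 2.39-fold. Of 32 mitosis genes, 29 rose, among them CENPF (1.86-fold), TOP2A (1.79-fold) and CCNB1 (1.73-fold), and 0 fell. Of 32 interferon response genes, 18 fell, among them OAS1 (1.87-fold) and ISG20 (1.69-fold), and 0 rose. Of 29 S phase genes, 10 fell, among them MCM2 (1.64-fold) and MCM5 (1.62-fold), and 1 rose. Of 33 junction genes, 12 rose, with the desmosomal DSG3 (2.20-fold) and DSC3 (2.07-fold) in the lead, and 3 fell. Of 29 proteolysis genes, 10 fell, among them MMP3 (1.86-fold) and PLAUR (1.66-fold), and 2 rose. Among markers of other cell types, 4 of 12 endothelial genes fell, among them CLDN5 (1.85-fold) and ENG (1.53-fold), and 0 rose. Of 12 fibroblast markers, 3 rose, led by COL1A1 (1.53-fold), and FBLN1 fell 1.31-fold. Of 13 leukocyte markers, CD68 fell 2.24-fold and 0 rose.

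In total 3820 genes differed between 72 h and 48 h with GFP (limma, Benjamini-Hochberg), 1959 higher and 1861 lower at 72 h. Camera with Benjamini-Hochberg adjustment gave adjusted p = 2.10e-24 for mitosis, 6.91e-10 for interferon response, 0.00342 for S phase, 0.00355 for proteolysis and 0.00626 for junctions. With an estimated correlation 0 of these 5 lists passed, 3 of the 28 lists had an unadjusted p under 0.05, and mitosis had adjusted p = 0.0599 with an estimated correlation. Without GFP array 1 of 48 h, 2545 genes passed.

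Both cell lines were then set side by side to ask which genes differ in opposite directions when ERG is added and when it is targeted. Of 301 genes lower in the arrays labelled ERG shRNA and measured in both lines, 43 were higher with GFP-ERG, where 20.6 would be expected. The odds ratio was 2.32 (95% interval 1.63 to 3.23, Fisher's exact test, p = 4.43e-06, Benjamini-Hochberg adjusted p = 1.77e-05 over 16 overlaps). Fisher's exact test takes genes as independent. Where genes move together, its intervals are too narrow and its p-values too small, here and for the other overlaps. The genes with the largest changes in both were MGP (-2.38 in VCaP and 0.91 in RWPE1, log2), FZD4 (-1.05 and 0.80), SERF2 (-1.87 and 0.79), UQCC2 (-1.61 and 0.76) and TNFRSF14 (-0.67 and 0.80). ST6GAL1, ROMO1, MT1F, SOD2 and ID3 followed. MT1F was higher with GFP-ERG at 48 h (1.11) but not at 72 h (-0.11). The other RWPE1 probe of ST6GAL1, dim at 6.54, changed by -0.04. Of 275 genes higher in the arrays labelled ERG shRNA, 24 were lower with GFP-ERG against 15.3 expected (odds ratio 1.64, interval 1.02 to 2.51, Fisher's exact test, p = 0.0323, Benjamini-Hochberg adjusted p = 0.0647 over the 16 overlaps). These included KCNK3 (0.99 in VCaP and -0.62 in RWPE1), CADM1 (0.87 and -0.61), GOSR1 (0.63 and -0.59) and BSN (0.93 and -0.41). Overlaps in the same direction held 10 lower genes against 16.8 expected (odds ratio 0.58, interval 0.27 to 1.08) and 14 higher genes against 18.8 (odds ratio 0.73, interval 0.39 to 1.25). Across all 16251 genes, which are not independent replicates, the fold changes had Pearson's r = -0.06 and Spearman's rho = -0.05 for the mean of both times. They had r = -0.00302 and rho = 0.03 for 48 h, and r = -0.11 and rho = -0.12 for 72 h. With the block for array number, without scramble array 1 or without scramble array 2, limma called 0 genes in VCaP (3612, 2251 and 1913 at an unadjusted p under 0.05), so that these overlaps could not be computed. The directions in VCaP are those of the labels, against which the ERG probe went.

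**Figure D3:**
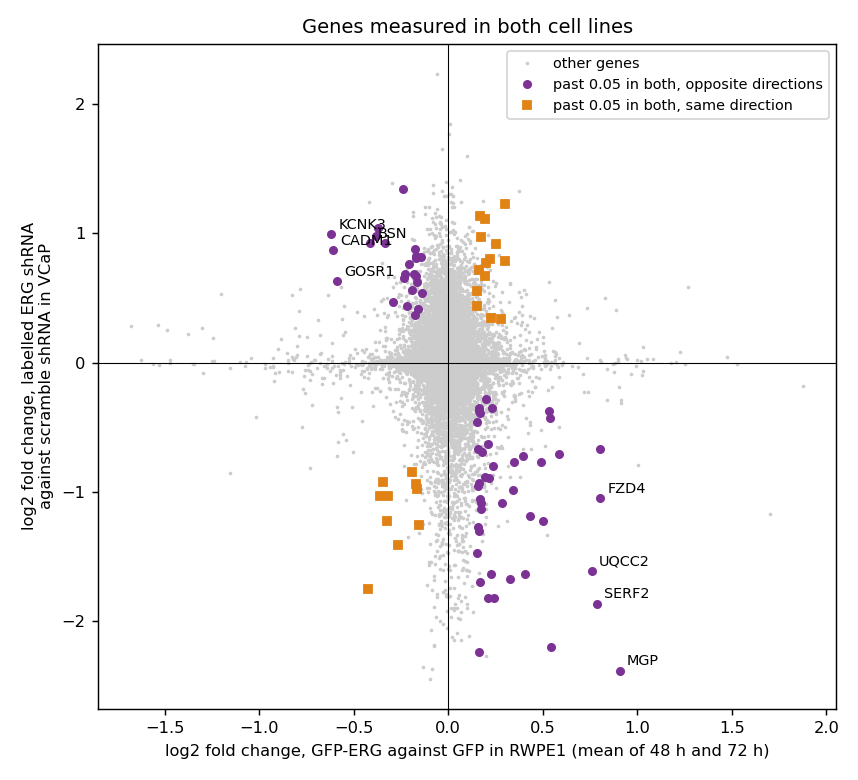
Log2 fold change of each gene measured in both lines, GFP-ERG against GFP in RWPE1 (horizontal) and arrays labelled ERG shRNA against scramble in VCaP (vertical); purple points passed adjusted p 0.05 in both in opposite directions, orange squares in both in the same direction, grey points are all other genes. Below and to the right of the centre lie 43 purple points, among them MGP, SERF2, UQCC2 and FZD4, and above and to the left lie 24.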

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

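The GFP-ERG effect differed between 72 h and 48 h for 79 genes by the test of the difference itself (limma, Benjamini-Hochberg, over 16591 genes). The log2 difference of the effect, 72 h minus 48 h, was 1.02 for HEY1, 0.99 for RGS4, 0.92 for SHISA2, 0.85 for TNFAIP6 and 0.76 for SERPINA3. It was -1.43 for PI3, -1.22 for MT1F, -1.07 for CA2, -0.91 for HBA1 and -0.83 for CYP1A1. SERPINA3 moved from 0.08 at 48 h to 0.85 at 72 h, and CYP1A1 from 0.27 to -0.56.

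Probes with no gene symbol also carried signal that the comparisons by gene leave out. In VCaP, 52 of 2692 such probes passed adjusted p 0.05 in a limma fit of all probes with Benjamini-Hochberg adjustment, 27 higher and 25 lower in the arrays labelled ERG shRNA. In RWPE1, 176 of 2257 passed for the mean of both times, 84 higher and 92 lower with GFP-ERG. The largest such change in RWPE1 was 1.78 log2 units.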

How the results depend on the processing

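All settings were planned before the data were examined. No result reversed. Quantile normalization and a floor of 6 left every count, ERG probe and overlap on its side of the threshold, but could move little. The values already had nearly equal distributions within a table, and the lowest values lay at 5.95 to 6.02 in RWPE1 and 7.44 in VCaP, near or above the floor. The odds ratio for genes lower in VCaP and higher with GFP-ERG stayed past the threshold in the other settings with calls in both lines. With a change of at least 1 log2 unit required, 151 genes were lower in VCaP and 17 higher with GFP-ERG. No gene was then shared in either opposite direction, and MGP came nearest with 0.91 in RWPE1. Stricter thresholds call fewer genes by construction, and for the other changes the cause was not tested. With 0 calls in VCaP under the block and at adjusted p 0.01, overlaps between the lines could not be computed there.

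At adjusted p 0.01, limma called 0 genes in VCaP (3651 had an unadjusted p under 0.05), 852 for GFP-ERG at 48 h, 613 at 72 h, 1304 for the mean and 39 for the difference between times. With a change of at least 1 log2 unit as well as adjusted p 0.05, the counts were 191 in VCaP, 56, 46, 45 and 4 for those in RWPE1, and 72 for 72 h against 48 h. In VCaP the filter on dim genes gave 1007 genes and a trended, robust variance 1705. The arrays of the comparison alone, with no term for time, gave 192 genes for the mean of both times.

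Array numbers gave little sign of pairing in RWPE1, where the deviations of same-numbered arrays from their group means correlated between -0.06 and 0.08. In VCaP they correlated at 0.19, and a single pair of groups cannot settle whether the arrays were paired. With a replicate block, limma called 0 genes in VCaP, with 3612 at an unadjusted p under 0.05. The block also takes up residual degrees of freedom, of which the VCaP fit has 2 without it. The bright ERG probe then had a log2 fold change of 0.40 at adjusted p = 0.0998, and 0 lists passed at 72 h, with 4 at an unadjusted p under 0.05. In RWPE1 the block gave 1455 genes at 48 h, 1067 at 72 h, 2101 for the mean, 99 for the difference and 2880 for time. With the filter on dim genes that ERG probe kept its change of 0.40 at adjusted p = 0.0515 (limma, Benjamini-Hochberg).

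With an estimated correlation camera called 0 lists in VCaP, at 48 h, at 72 h, for the difference and for time, with 0, 0, 1, 2 and 3 at an unadjusted p under 0.05. That test had few residual degrees of freedom and could pass few lists. Fry called 8 lists in VCaP, where camera called 6, 12 at 48 h, 3 at 72 h, 8 for the mean, 0 for the difference (6 at an unadjusted p under 0.05) and 14 for time. The filter on dim genes gave 2 lists at 48 h and 1 for the mean, median centring gave 2 at 72 h, and the arrays of the 72 h comparison alone gave 0, with 5 at an unadjusted p under 0.05. Using 48 h alone, the odds ratio for genes higher in VCaP and lower with GFP-ERG was 1.46.

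Leaving out 1 array at a time, with the lone array assumed to vary like the other groups, gave 0 to 2254 genes in VCaP (0 without scramble array 1 or 2, where limma left 2251 and 1913 at an unadjusted p under 0.05). The ranges were 798 to 1399 genes at 48 h, 532 to 1228 at 72 h, 32 to 144 for the difference and 2545 to 4101 for time. The change of the bright ERG probe was 0.37 to 0.43, and the odds ratio for genes higher in VCaP and lower with GFP-ERG 1.22 to 1.92. For the overlap of both times it was 29.5 to 90.2 for higher and 56.1 to 269 for lower genes. Camera called 0 to 1 lists at 48 h, 0 to 2 at 72 h, 0 to 1 for the mean and 1 to 3 for the difference.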

Other observations

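All tests in this part were chosen after the results they bear on had been seen. Genes of the respiratory chain and ATP synthase formed a group that the lists did not cover. Of 80 such genes measured in VCaP, chosen by symbol after NDUFA3, NDUFA1 and ATP5MC1 had been seen among the lowest, 28 fell, 0 rose and 60 had a negative log2 fold change (limma, Benjamini-Hochberg). Their median was 10.43 and 10.45 in the arrays labelled ERG shRNA and 11.53 and 11.55 in the scramble arrays, and their median log2 fold change was -1.02. In RWPE1, 4 of 84 rose and 2 fell with GFP-ERG.

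Genes with a short span in the genome were lower in the arrays labelled ERG shRNA. Over 9366 genes at or above the median level, the Spearman correlation of gene span with log2 fold change was 0.32. The medians were -0.12 for the 20% of genes with the shortest span and 0.13 for the 20% with the longest. Between both arrays labelled ERG shRNA the correlation was 0.22, between the scramble arrays -0.13, and for GFP-ERG in RWPE1 -0.01. Gene span and level, as matched here, did not account for the median fall of the respiratory chain genes. Set against 100 genes matched to each on span and level, which had a median change of -0.01, the log2 change was -0.907 (95% bootstrap interval -1.12 to -0.33). That interval resamples genes within the same arrays, and the genes that prompted the choice of the group were not taken out. A single aberrant array is argued against too, because the median difference between the arrays labelled ERG shRNA was -0.0743. In RWPE1 their median change with GFP-ERG was 0.00353 and the upper quartile 0.0528, which argues against a rise there as large as the difference in VCaP, while a smaller effect or one in VCaP alone stays open. Transcript length and RNA quality, which could also differ between groups, were not tested.

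Of 111 genes lower by at least 1.5-fold with GFP-ERG in RWPE1, 18 had other probes, and on these the fall was not seen. Their used probes changed by a median of -0.84 log2 units, their 22 other probes by 0.00447, and 0 of these passed (limma, Benjamini-Hochberg), as a signal specific to 1 probe would have it. The other probes of the lower genes were dimmer than in other genes of that level, with a median gap of 3.30 log2 units against 2.53 in 5000 random draws of matched genes (95th percentile 3.01), and only 4 of the 22 lay above the median level of the table, so that dimness may hide falls on the rest. Binding of these probes to other sequence and a change of 1 transcript form were not separated, and either may underlie the falls.

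The higher ERG probe in the arrays labelled ERG shRNA could come from exchanged labels of the VCaP groups. If ERG acts alike in both lines, genes lower in those arrays would then be lower with GFP-ERG too. Their odds ratio of being lower was 0.577 (interval 0.27 to 1.08) and that of being higher 2.32, which argues against an exchange under that assumption. The intervals of these odds ratios take genes as independent, so the strength of this argument is uncertain. The change of the ERG probe lay at the 84.0th percentile of 200 genes matched on gene span and level, inside their middle 95% (-0.52 to 0.71), so that a rise of this size also occurs among genes of like span and level. Which transcripts this probe reads stays open.

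For GFP-ERG against GFP in RWPE1, a fit with a term for time called 1812 genes. Of the 34 splits of the 8 arrays into 4 and 4 that such a fit allows, 1 gave as many, the real one, and the highest of the others gave 0. These splits also exchange arrays between 48 h and 72 h, which are not interchangeable. In the other splits the GFP-ERG difference enters the spread and lowers the calls. The splits therefore give no probability for the real grouping. Without the term, the split by time called 3874 genes and the real one 192, which points to the strong structure by time, and the highest of the other splits gave 0.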
